A study of Mus musculus with 15 samples.

How the data were processed

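RNA was measured in 15 submandibular gland samples from male C57BL/6 mice aged 8 to 10 weeks, 3 per group in 5 groups. The groups were nontreated (NT), irradiated with 15 Gy at the gland region and collected at day 4 (IR_4d) or day 30 (IR_30d), and irradiated, given iEVs into the gland each week from day 1, and collected at day 4 (IR_iEV_4d) or day 30 (IR_iEV_30d). The labels do not spell out iEV, and the series title speaks of mesenchymal stem cell extracellular vesicles. None of the 5 groups is named as injected with vehicle or as given iEVs without irradiation. A difference between IR_iEV and IR may therefore come from the injection as well as from the iEVs. It is called an iEV change or effect for short. The labels do not state when the nontreated glands were collected, so IR and NT may also differ in age at collection. They do not state whether each sample came from its own mouse either. The p-values therefore measure the spread between these samples, which may be partly technical. RNA was extracted with TRIzol, and stranded libraries were made with the NEXTFLEX Rapid Directional kit.

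The authors deposited a table of whole-number read counts per gene symbol, with 1 column per library. Their notes name TopHat, HTSeq, DESeq2 and the mouse genome build GRCm39, without versions. The counts were not divided by size factors: totals differed between libraries, from 29082798 to 52201098, and the distribution rose with the total. The table held 21013 gene symbols, 15 of them with no count in any library. The strand setting, the annotation and the handling of reads that map to several places are not stated. No annotation of that build was at hand, so no coordinates are given; an annotation of the preceding mouse build served only for exonic lengths, found for 91.6% of the tested genes.

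Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, a low-count filter (filterByExpr, minimum count 10 and minimum total 15), and a robust quasi-likelihood F test in 1 model of all 15 libraries with 10 residual degrees of freedom. The filter left 16042 genes. P-values were adjusted by Benjamini-Hochberg within each of 8 comparisons, with a threshold of 0.05. Changes are log2 ratios with a standard error (SE), derived as the absolute log2 ratio divided by the square root of the F statistic. Levels are CPM (counts scaled to the effective library size) as mean ± SD of 3 libraries. Precision is limited by the 3 libraries per group as well as by these totals. The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 1.5-fold, all with a mean of at least 1 CPM. In the 4 main comparisons it recovered 81, 85, 68 and 72% of the former and 37, 32, 36 and 37% of the latter. False calls numbered 3, 7, 4 and 9. Genes varied independently in the simulation, and changes at lower counts were not tested.

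A set of 40 gene lists was fixed before the data were examined, and each was tested with limma 3.58.1 camera on log2 CPM with prior count 2 and a preset correlation between genes of 0.01, adjusted over the 40 lists within a comparison. Each list test was repeated with the correlation estimated from the data. Members were also counted when their p-values were adjusted over the list alone. The genes named were also set by a rule fixed beforehand. For each main comparison (IR against NT and IR_iEV against IR on each day) it took the 8 largest rises and 8 largest falls among genes past the threshold with groups that did not overlap (chance gives 10% for 3 against 3) and a mean of at least 2 CPM. Predicted genes, clone names, immunoglobulin, T cell receptor and mitochondrial genes were excluded. It added up to 4 members of each list with the lowest p, and Cdkn1a, Aqp5, Gli1 and Aldh3a1. Where fewer than 5 genes passed in a direction, the 5 with the lowest p are named as not passed. The rule gave far more genes than are named below, which were picked from its result.

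Each library was also placed on an irradiation axis, the vector of log2 changes over the genes past the threshold, with the NT mean at 0 and the IR mean at 1. Positions on the axis of the other day were compared with a two-sided exact permutation test, whose smallest p is 0.1 for 3 against 3. Because IR against NT and IR_iEV against IR share the IR libraries, the share of genes with opposite changes was set against 100 simulated draws in which iEVs changed nothing. The position of iEV libraries on the axis of their own day and the number of genes past both thresholds were set against the same draws, a comparison chosen after the data were seen. These have no permutation test, since the IR libraries define the axis.

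Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors or upper quartile scaling in edgeR, no low-count filter, a mean of at least 5 CPM, a separate fit of each comparison, the replicate number as a block, and leaving out each library in turn. Replicate numbers did not pair the libraries: 5 of 30 same-number pairs had correlated residuals above 0.1. A pair of alternatives was added after the data were seen. In the first, the levels of sublingual gland and adipose marker lists were covariates. In the second, the 6 libraries with a sublingual level above 2 (mean log2 CPM) were left out, so IR_4d and IR_iEV_4d keep 1 library each, which is assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.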

Results

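Bulk RNA sequencing covered 15 submandibular gland libraries in 5 groups of 3: NT, IR_4d, IR_iEV_4d, IR_30d and IR_iEV_30d. Total counts per library ran from 29082798 to 52201098. The 10 most counted genes took 39.9 to 50.4% of a library, as secretory products dominate a salivary gland. Values are log2 changes ± SE or mean CPM ± SD with n = 3 per group. Adjusted p-values are from edgeR for genes and from camera for gene lists.

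Libraries differed in markers of tissues that border the gland. The sublingual list stood at 2.81 (mean log2 CPM) in NT replicate 1, at 5.73 and 4.02 in IR_4d replicates 1 and 2, at 4.31 and 4.98 in IR_iEV_4d replicates 2 and 3 and at 4.43 in IR_iEV_30d replicate 2. In the other 9 libraries it lay between -1.63 and 0.28. Dcpp3, a sublingual secretory product, had 3478 CPM in IR_4d replicate 1 and 0.111 CPM in NT replicate 3. Adipose markers were highest in IR_4d replicate 3 (3.55), IR_iEV_4d replicate 1 (3.31) and IR_iEV_4d replicate 2 (4.78), and muscle markers in IR_iEV_4d replicate 2 (2.14). The parotid list, 5 of whose 9 genes are also in another list, ran from 2.49 to 3.49 in NT, 3.83 to 8.22 in IR_4d and 7.05 to 8.26 in IR_iEV_4d. It ran from 3.39 to 5.56 in IR_30d and 3.29 to 6.92 in IR_iEV_30d. Bpifa2, a parotid secretory product, had 0.252 CPM in NT replicate 2 and 4911 CPM in IR_4d replicate 1. The alternatives for neighbouring tissue given below for counts and list tests covered the sublingual and adipose lists, not the parotid list.

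**Figure D1:**
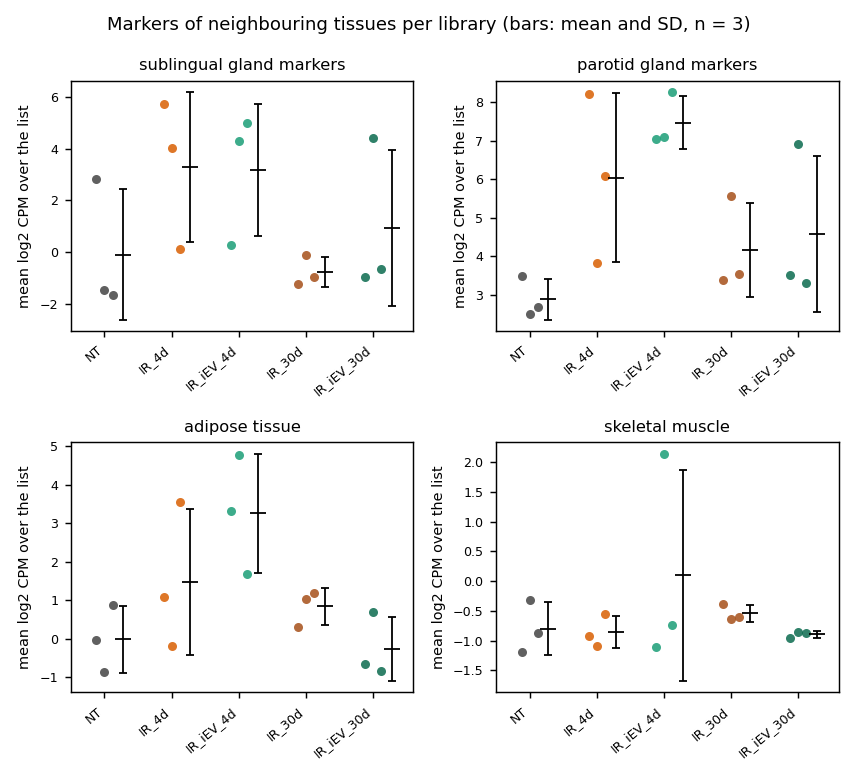
Level of 4 marker lists of neighbouring tissues in each of the 15 libraries, as mean log2 CPM over the list (y axis) by group (x axis); points are libraries and bars are mean and SD. Sublingual levels reach 5.73 in IR_4d and 4.43 in IR_iEV_30d replicate 2.

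The first question was what irradiation changed by day 4. IR_4d glands showed a strong rise of p53 target genes: Cdkn1a, an inhibitor of cyclin-dependent kinases, went from 2.57 ± 0.705 to 56.1 ± 10.6 CPM (log2 4.43 ± 0.26). The stress cytokine Gdf15 went from 1.35 ± 0.404 to 33.4 ± 3.47 CPM (log2 4.64 ± 0.41). The lists of interferon-stimulated genes, antigen presentation and T and NK cell markers were lower by camera, with 7 of 51, 6 of 25 and 2 of 26 members past the threshold. Of these 3 lists, T and NK cells alone kept the call with an estimated correlation. Of 16042 genes, 224 changed, 134 higher and 90 lower. Of the 40 p53 targets, 24 rose and 16 did not pass, with a median of 0.97 (camera adjusted p = 1.28e-41, and adjusted p = 0.000148 with an estimated correlation). Adjusted over the list alone, 26 rose and 1 fell. Besides Cdkn1a and Gdf15 these included Eda2r, a receptor of the TNF receptor family (2.63 ± 0.15), Aen, an apoptosis-enhancing nuclease (2.16 ± 0.09), Phlda3 (2.05 ± 0.13) and Zmat3 (1.61 ± 0.11). Among 31 apoptosis genes 4 rose and 1 fell, or 5 and 1 adjusted over the list alone. The proapoptotic Bax (1.36 ± 0.11), Bbc3 (1.04 ± 0.15) and the death receptor Tnfrsf10b (1.95 ± 0.25) were higher and Bmf was lower (-0.97 ± 0.13). The list itself did not pass (camera adjusted p = 0.572). Further large rises were in Inka2 (2.91), Ddias (2.78), Dynlt2a1 (2.51), the DNA repair gene Mgmt (2.42) and Gtse1 (2.36).

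Of the 51 interferon-stimulated genes 7 fell in IR_4d and 14 did when adjusted over the list alone (median -0.39, camera adjusted p = 2.87e-12, and adjusted p = 0.317 with an estimated correlation). Examples were Oasl1 (-1.45 ± 0.32) and Cmpk2, which went from 4.09 ± 0.850 to 1.65 ± 0.580 CPM. Irf7, a transcription factor of the interferon response, went from 13.2 ± 3.47 to 6.30 ± 0.734 CPM. Of 25 antigen presentation genes 6 fell, or 10 adjusted over the list alone (median -0.35, camera adjusted p = 2.48e-07, and adjusted p = 0.388 with an estimated correlation). They included the MHC class II genes H2-Eb1 (-0.91 ± 0.10) and H2-Aa (-0.91 ± 0.11) and their chaperone Cd74 (-0.79 ± 0.11). The T and NK cell list had a median of -1.15, with 2 of 26 members lower and 7 adjusted over the list alone (camera adjusted p = 1.9e-12, and adjusted p = 0.00981 with an estimated correlation). The genes that fell were Il2rb (-1.21 ± 0.23) and Lck (-2.14 ± 0.45). Macrophage markers had 4 of 34 members lower and 6 adjusted over the list alone (median -0.19, camera adjusted p = 0.00314, and adjusted p = 0.536 with an estimated correlation). Among them was Ccr2, a chemokine receptor of monocytes (-1.28 ± 0.24). In lipid synthesis 2 of 32 genes rose, Scd2 (1.67 ± 0.21) and Srebf1 (0.94 ± 0.14), also 2 adjusted over the list alone (median 0.51, camera adjusted p = 1.09e-07, and adjusted p = 0.504 with an estimated correlation). Beside them the adipose list had a median of 2.56 (camera adjusted p = 0.00616, and adjusted p = 0.696 with an estimated correlation). The adipose tissue adjusted p was 0.756 without IR_4d replicate 3 and 0.0649 without NT replicate 2, and 0.397, in the other direction, with sublingual and adipose levels as covariates. The parotid list had a median of 5.57, with 4 of 7 members higher and 2 lower adjusted over the list alone, and did not pass (camera adjusted p = 0.0961). The antioxidant regulator Nfe2l2 rose (0.68 ± 0.08). Other large falls were Klhl33 (-2.12), Bcat1 (-1.78), Tgm5 (-1.28) and Trib3 (-1.19). Aqp5, the water channel of acinar cells, stood at 282 ± 9.16 in NT and 333 ± 26.7 CPM in IR_4d (adjusted p = 0.327). The count of 224 became 386 without NT replicate 1, 143 and 116 without NT replicates 2 and 3, and 148, 131 and 123 without IR_4d replicates 1 to 3. It was 435 with DESeq2, 81 with sublingual and adipose levels as covariates and 127 without the 6 libraries high in sublingual markers. Bcat1, Oasl1, Cmpk2, Ccr2, Il2rb, Trib3, Irf7 and Lck each lost their call without at least 1 of the 6 libraries, and each of the 6 ended at least 1 of these calls. Their highest adjusted p ran from 0.0536 for Cmpk2, without NT replicate 3, to 0.216 for Trib3. With sublingual and adipose levels as covariates these 8 genes lost their call too, from 0.068 for Cmpk2 to 0.484 for Trib3. Without the libraries high in sublingual markers Bcat1, Oasl1, Ccr2, Trib3, Lck, Bmf and Bbc3 did, from 0.0732 for Bmf to 0.416 for Bcat1.

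The second question was how IR_30d differed from NT, whose collection day is not stated, so that age may differ as well as irradiation. In IR_30d the p53 targets were higher than in NT, the 1 list of 17 called by camera that kept its call with an estimated correlation. Called without it were the lists of interferon-stimulated genes, macrophage markers and products of the granular convoluted tubules, the ducts that secrete kallikreins in male mice. Lcn2, an iron-binding acute phase protein, went from 24.5 ± 1.72 to 135 ± 34.6 CPM (log2 2.46 ± 0.31). Nfkb2, a subunit of NF-kB, went from 35.4 ± 6.14 to 84.7 ± 5.66 CPM (1.26 ± 0.10). Aqp5 fell from 282 ± 9.16 to 206 ± 12.5 CPM (-0.45 ± 0.10). In all, 718 genes changed, 511 higher and 207 lower. Of 40 p53 targets 23 rose and 17 did not pass, or 25 rose adjusted over the list alone (median 0.83, camera adjusted p = 2.03e-27, and adjusted p = 0.000992 with an estimated correlation). Cdkn1a was at 33.9 ± 10.8 CPM (3.70 ± 0.25) and Gdf15 at 41.8 ± 8.98 CPM (4.96 ± 0.41).

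Of 51 interferon-stimulated genes 23 rose and 42 did adjusted over the list alone (median 0.84, camera adjusted p = 9.45e-28, and adjusted p = 0.0609 with an estimated correlation). Examples were Oas3 (2.80 ± 0.34), Oas2 (2.04 ± 0.26) and Ifit3, at 13.6 ± 1.77 CPM against 4.81 ± 1.23 in NT. The nucleic acid sensor Zbp1 also rose (2.17 ± 0.35). Of 25 antigen presentation genes 15 rose, or 20 adjusted over the list alone (median 0.74, camera adjusted p = 1.14e-19, and adjusted p = 0.0609 with an estimated correlation). They included H2-K1 (0.95 ± 0.10) and the peptide transporter Tap1 (0.91 ± 0.11). Of 34 macrophage markers 19 rose (median 0.87, camera adjusted p = 1.02e-15, and adjusted p = 0.126 with an estimated correlation). Among them were the complement genes C1qa (1.01 ± 0.13) and C1qb (0.97 ± 0.12) and the protease Ctss (1.10 ± 0.13). Adjusted over the list alone 22 rose and 2 fell. Of 27 tubule products 16 rose and 1 fell, or 18 and 1 adjusted over the list alone (median 1.24, camera adjusted p = 5.46e-14, and adjusted p = 0.162 with an estimated correlation). Klk1b22 (1.32 ± 0.17), Klk1b21 (1.37 ± 0.19) and Klk1b26 (1.06 ± 0.17) rose, while Klk1 fell (-1.56 ± 0.25). The Klk1b genes are near-identical paralogs, so the split of reads among them is uncertain. The angiogenic factor Vegfa (0.87 ± 0.14) and Fgf1 (0.78 ± 0.12) also rose.

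Of 42 extracellular matrix genes 1 rose and 10 fell, or 2 and 19 adjusted over the list alone (median -0.26, camera adjusted p = 2.87e-05, and adjusted p = 0.309 with an estimated correlation). The collagens Col1a1 (-0.70 ± 0.13) and Col15a1 (-0.79 ± 0.13) and the fibroblast receptor Pdgfra (-0.60 ± 0.12) were lower and Mmp2, a matrix protease, was higher (0.67 ± 0.13). Of 33 acinar secretory genes 1 rose and 4 fell, or 1 and 5 adjusted over the list alone. Their median was -0.23 and their mean 0.28, so the 2 differ in sign (camera down, adjusted p = 0.0125, and adjusted p = 0.158 with an estimated correlation). Without NT replicate 1 the adjusted p of the acinar secretory genes was 0.0797, and without the libraries high in sublingual markers 0.109. The detoxifying enzyme Gsta4 was also lower (-1.23 ± 0.18), as was Nr1d1, a repressor of the circadian clock (-2.90 ± 0.65). Other large falls were Ccn4 (-1.94), Amer2 (-1.85), Crabp1 (-1.63), Tubb2b (-1.46), Prrg3 (-1.33) and Tmigd1 (-1.28). Other large rises were Spock1 (3.45), Crisp1 (2.75) and Syt16 (2.66). The count of 718 became 460 without NT replicate 1, 355 without IR_30d replicate 2 and 360 without IR_30d replicate 3, and was 1082 with DESeq2. Crisp1 and Syt16 lost their call without each library in turn (highest adjusted p 0.144 and 0.113). The call ended for Tmigd1 without all but NT replicate 2 (0.183), Nr1d1 without NT replicate 2 or 3 or IR_30d replicate 2 or 3 (0.136) and Aqp5 without IR_30d replicate 1 (0.0671). With sublingual and adipose levels as covariates Crisp1, Nr1d1 and Tmigd1 did not pass (0.0899, 0.0714 and 0.0886), nor did Nr1d1 and Tmigd1 without the libraries high in sublingual markers (0.138 and 0.192).

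**Figure D2:**
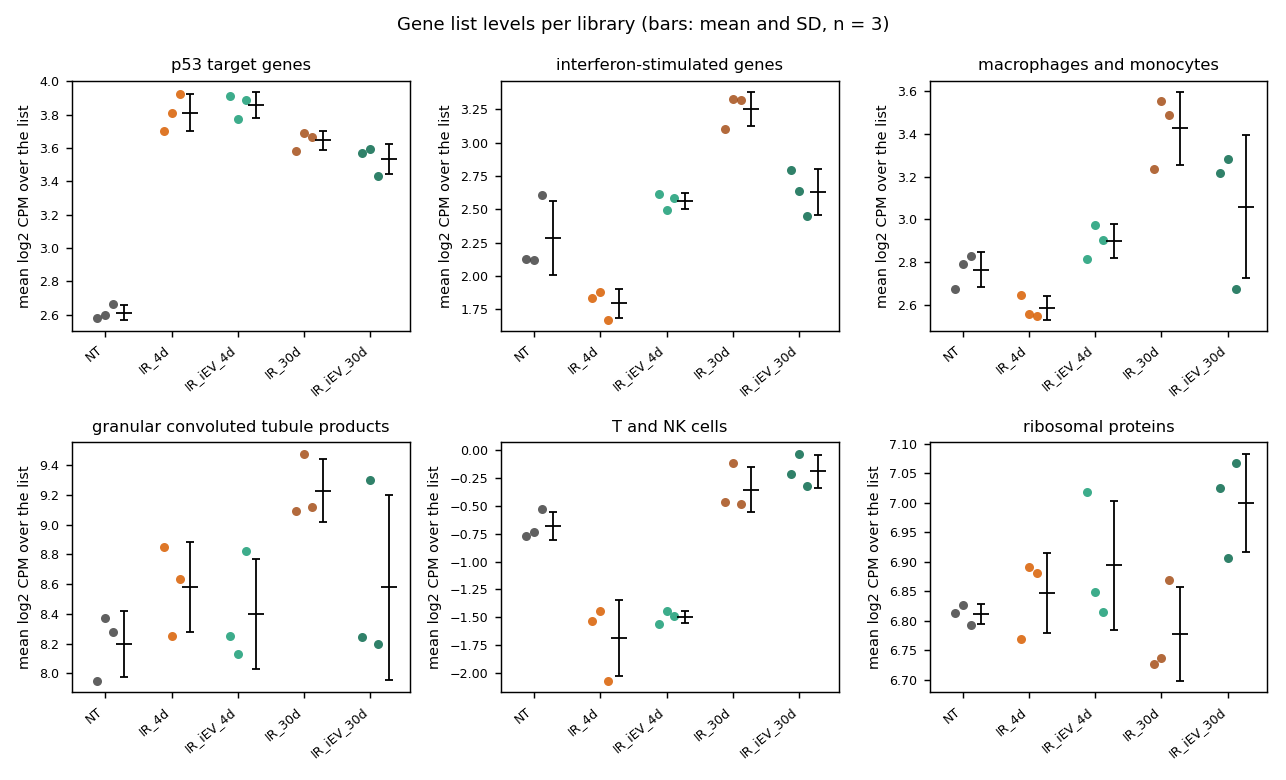
Level of 6 gene lists in each of the 15 libraries, as mean log2 CPM over the list (y axis, which does not start at 0) by group (x axis); points are libraries and bars are mean and SD. The p53 targets stand near 2.61 in NT and 3.81 in IR_4d, and the interferon list at 1.79 in IR_4d, 2.56 in IR_iEV_4d, 3.25 in IR_30d and 2.63 in IR_iEV_30d.

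The third question was how IR_iEV_4d differed from IR_4d, a contrast that may hold the injection as well as the iEVs. A small set of interferon-related genes was higher in IR_iEV_4d than in IR_4d. Ifit3, an antiviral effector, went from 2.42 ± 0.217 to 6.97 ± 0.938 CPM (log2 1.52 ± 0.21, adjusted p = 0.0104) and Irf7 from 6.30 ± 0.734 to 17.0 ± 0.822 CPM (1.43 ± 0.20). The NT levels were 4.81 ± 1.23 and 13.2 ± 3.47 CPM. The genes past the threshold were 5, namely these 2, Rtp4 (1.52 ± 0.21), the virus-tethering protein Bst2 (0.89 ± 0.14) and Sdc3, a heparan sulfate proteoglycan (0.72 ± 0.12). With edgeR 0 genes were lower, while 1093 genes in either direction had an unadjusted p under 0.05. DESeq2 called 23 higher and 7 lower, and limma-voom called 0 (1072 at an unadjusted p under 0.05). The lowest p-values among lower genes that did not pass belonged to Lactb2 (-0.38), Shank2 (-0.36), Etl4 (-0.41), Prkca (-0.57) and Dhcr7 (-0.62). Of 51 interferon-stimulated genes 4 rose and 47 did not pass, whereas 34 rose adjusted over the list alone (median 0.71, camera adjusted p = 7.08e-36, and adjusted p = 0.0637 with an estimated correlation). The antigen presentation list had a median of 0.27, with 3 of 25 members higher adjusted over the list alone (camera adjusted p = 5.31e-07, and adjusted p = 0.474 with an estimated correlation). The macrophage list had a median of 0.27, with 8 of 34 higher adjusted over the list alone (camera adjusted p = 3.5e-07, and adjusted p = 0.474 with an estimated correlation). The lipid synthesis list had a median of -0.40, with 1 of 32 members lower adjusted over the list alone (camera adjusted p = 1.95e-05, and adjusted p = 0.669 with an estimated correlation). The antioxidant list had a median of 0.19, with 8 of 42 higher adjusted over the list alone (camera adjusted p = 2e-07, and adjusted p = 0.474 with an estimated correlation). Beside these, adipose markers had a median of 1.44 (camera adjusted p = 1.73e-07, and adjusted p = 0.556 with an estimated correlation). Skeletal muscle markers had a median of 2.62 (camera adjusted p = 0.00351, and adjusted p = 0.669 with an estimated correlation), and an adjusted p of 0.933 without IR_iEV_4d replicate 2. With sublingual and adipose levels as covariates the adjusted p was 0.785 for adipose tissue and 0.239 for skeletal muscle. Without the libraries high in sublingual markers, where both groups keep 1 library, both lists changed direction. Among p53 targets the median was 0.02 (camera adjusted p = 0.145). Cdkn1a had 56.1 ± 10.6 CPM in IR_4d and 77.1 ± 7.88 in IR_iEV_4d (adjusted p = 0.727), and Aqp5 333 ± 26.7 and 320.3 ± 27.4. The count of 5 became 0 without IR_4d replicate 1 or 3 or IR_iEV_4d replicate 1, 1 without IR_4d replicate 2 or IR_iEV_4d replicate 2 and 7 without IR_iEV_4d replicate 3. The genes at an unadjusted p under 0.05 in these fits numbered 747, 937, 1020, 941, 668 and 1546. The count was 2 at a mean of at least 5 CPM and 3 in its own fit. It was 0 with sublingual and adipose levels as covariates (713 at an unadjusted p under 0.05). Without the 6 libraries high in sublingual markers 1 gene was higher and 4 lower, of which 0 were among these 5 (703 at an unadjusted p under 0.05).

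The fourth question was how IR_iEV_30d differed from IR_30d, a contrast that may likewise hold the injection as well as the iEVs. By camera the lists of tubule products, interferon-stimulated genes and secretion machinery were lower in IR_iEV_30d than in IR_30d, and ribosomal protein genes were higher. With an estimated correlation none of the 11 lists called kept its call, and 6 lists passed with fry. Lcn2 went from 135 ± 34.6 to 26.6 ± 9.80 CPM (log2 -2.35 ± 0.31), against 24.5 ± 1.72 in NT. Nfkb2 went from 84.7 ± 5.66 to 40.1 ± 0.768 CPM (-1.08 ± 0.10), and Hsd11b1, which regenerates active glucocorticoid, from 115 ± 11.4 to 43.7 ± 4.61 CPM (-1.39 ± 0.15). Aqp5 rose from 206 ± 12.5 to 282 ± 32.4 CPM (0.45 ± 0.10, adjusted p = 0.0411), against 282 ± 9.16 in NT. In all, 128 genes changed, 27 higher and 101 lower. Of 27 tubule products 11 fell and 16 did not pass, and 1 rose and 17 fell adjusted over the list alone (median -0.83, camera adjusted p = 2.63e-10, and adjusted p = 0.372 with an estimated correlation). They included Klk1b27 (-1.73 ± 0.32), Klk1b8 (-1.76 ± 0.34), Klk1b21 (-1.18 ± 0.19) and Klk1b22 (-0.99 ± 0.17), whose reads are uncertain between paralogs. The level of this list was 9.30 (mean log2 CPM) in IR_iEV_30d replicate 2, the library with sublingual markers, against 8.24 and 8.20 in replicates 1 and 3. Vegfa (-0.83 ± 0.14) and Fgf1 (-0.60 ± 0.12) fell too.

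Of 51 interferon-stimulated genes 3 fell and 32 did adjusted over the list alone (median -0.64, camera adjusted p = 1.38e-17, and adjusted p = 0.16 with an estimated correlation). These 3 were Ifit3 (-1.07 ± 0.19), Oas2 (-1.14 ± 0.25) and Gbp3 (-0.97 ± 0.20). Of 34 macrophage markers 1 fell, Lyve1 (-1.28 ± 0.29), and 13 did adjusted over the list alone (median -0.42, camera adjusted p = 1.46e-07, and adjusted p = 0.444 with an estimated correlation). Of 43 genes of the unfolded protein response and secretion machinery 6 fell and 13 did adjusted over the list alone (median -0.22, camera adjusted p = 1.52e-08, and adjusted p = 0.16 with an estimated correlation). Among them were the chaperones Hspa5 (-0.69 ± 0.12) and Hyou1 (-0.60 ± 0.12). Others were Sel1l (-0.55 ± 0.09) and Edem1 (-0.54 ± 0.11), which act in the degradation of misfolded proteins. Of 57 ribosomal protein genes 1 rose, Rps23 (0.34 ± 0.07), and 33 did adjusted over the list alone (median 0.22, camera adjusted p = 3.91e-23, and adjusted p = 0.372 with an estimated correlation). Across genes, which are not independent replicates, exonic length and the change in this comparison had a Spearman correlation of -0.128, with shorter transcripts higher. The acinar list had a median of 0.31, with Aqp5 the member of 33 that rose and 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0048, and adjusted p = 0.16 with an estimated correlation). The acinar secretory genes had an adjusted p of 0.0711 with sublingual and adipose levels as covariates. The duct list had a median of 0.12, with Fxyd2, a regulator of the sodium pump, higher (76.6 ± 5.56 and 188 ± 74.2 CPM), and 5 of 35 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00175, and adjusted p = 0.16 with an estimated correlation). The p53 targets had a median of -0.13 (camera adjusted p = 0.242), and Cdkn1a stood at 33.9 ± 10.8 in IR_30d and 33.3 ± 2.51 CPM in IR_iEV_30d (adjusted p = 0.977). Other large rises were Trib2 (0.99), Kirrel3 (0.93), Zfp185 (0.73), Clmn (0.72), the metallothionein Mt1 (0.71), Bmf (0.68) and Prrg3 (0.65). Other large falls were Spock1 (-3.12), B3gnt5 (-1.46) and Castor1 (-1.27). The count of 128 became 69, 12 and 9 without IR_30d replicates 1 to 3 and 31, 199 and 27 without IR_iEV_30d replicates 1 to 3. It was 394 with DESeq2, 70 in its own fit, 75 with sublingual and adipose levels as covariates and 307 without the libraries high in sublingual markers. Hsd11b1, B3gnt5 and Nfkb2 passed without each of the 6 libraries, whereas each other gene named here as changed lost its call without IR_30d replicate 3, some also without other libraries. Their highest adjusted p over the 6 fits ran from 0.0526 for Lcn2 to 0.264 for Oas2, and 0.202 for Aqp5. With sublingual and adipose levels as covariates Klk1b27, Klk1b8, Prrg3, Bmf, Gbp3, Rps23, Fxyd2, Kirrel3, Aqp5 and Lyve1 lost their call, from 0.0548 for Klk1b27 to 0.107 for Lyve1. Without the libraries high in sublingual markers Kirrel3, Gbp3, Bmf, Prrg3 and Lyve1 did, from 0.0506 for Kirrel3 to 0.197 for Lyve1.

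**Figure D3:**
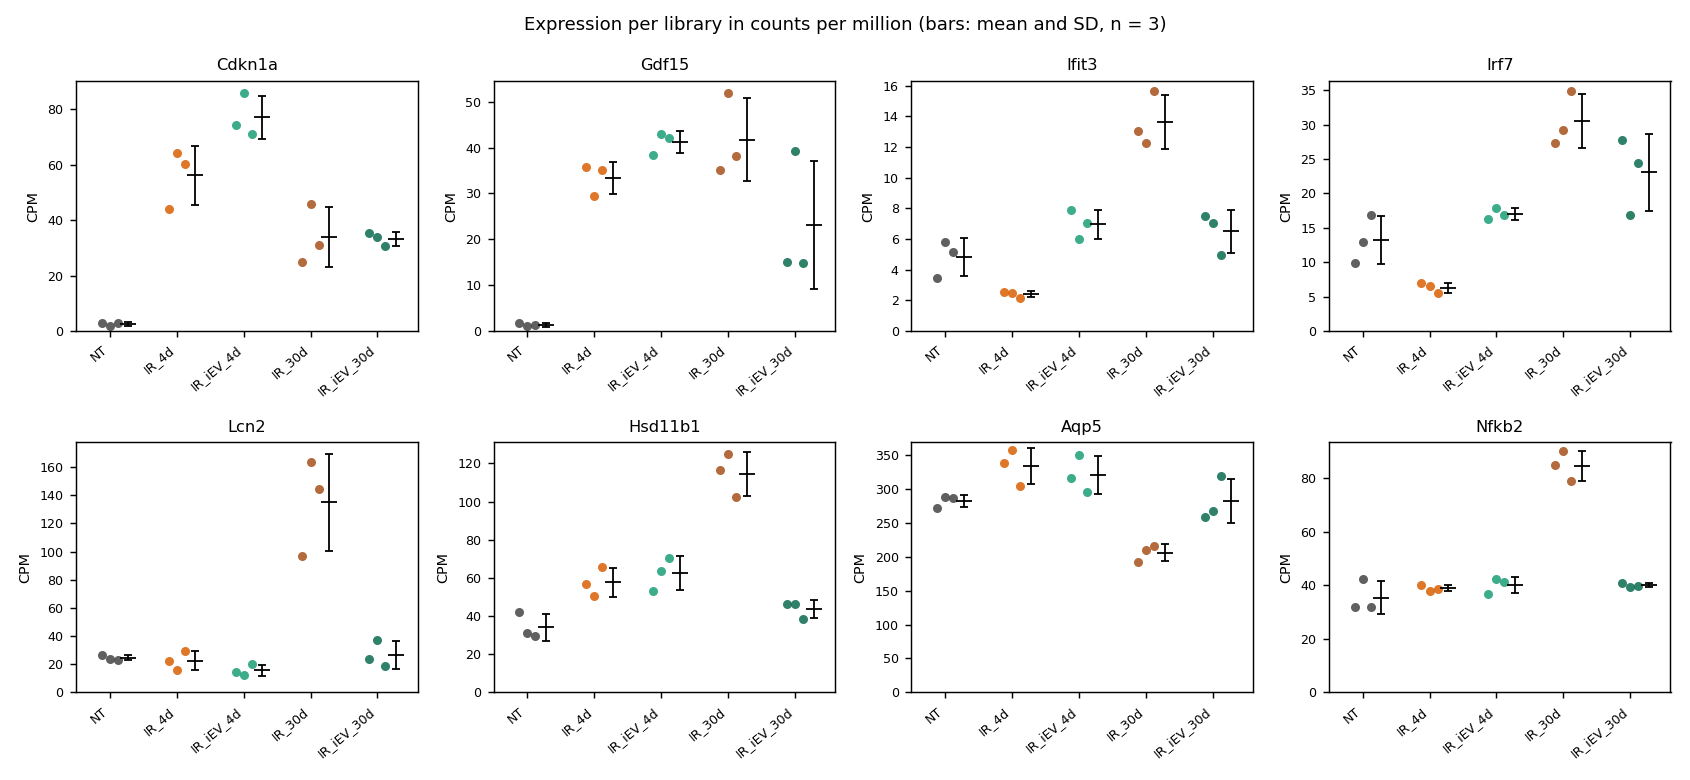
CPM (y axis, from 0) of 8 genes in each of the 15 libraries by group (x axis); points are libraries and bars are mean and SD. Cdkn1a is at 2.57 CPM in NT and at 56.1, 77.1, 33.9 and 33.3 CPM in the 4 irradiated groups.

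Whether iEVs moved the genes changed by irradiation back was measured in several ways. At day 30, 639 of the 718 genes changed by irradiation (89.0%) had an opposite iEV change, against 59.6% (SD 2.39, highest 64.7%) in simulated draws without an iEV effect, in which the shared IR libraries alone give opposite signs. At day 4 it was 139 of 224 genes (62.1%), against 59.9% (SD 3.99, highest 71.9%). Over all genes the covariance of the irradiation and iEV changes was -0.103 at day 30, below the draws (-0.0653 to -0.0496). At day 4 it was -0.0387, nearer to 0 than the draws (-0.0804 to -0.0583). The draws left out correlation between genes, so their spread is too small. They also took the observed changes of called genes as true and set the changes of all other genes to 0. In fits of 9 libraries they called 453 genes on average at day 30 and 146 at day 4, fewer than the observed 718 and 224. Their centre may therefore be off as well. Of the genes past the threshold in both comparisons at day 30, which share the IR_30d libraries, 83 were higher with irradiation and lower with iEVs, such as Lcn2 and Nfkb2, and 18 the other way round, such as Aqp5. Without IR_30d replicates 1 to 3 these counts were 51 and 5, 11 and 1, and 9 and 0, and without IR_iEV_30d replicates 1 to 3 they were 18 and 3, 114 and 28, and 23 and 4. Without NT replicates 1 to 3 they were 87 and 23, 74 and 11, and 60 and 10. Of the examples, Lcn2 and Aqp5 lost their iEV call without IR_30d replicate 3 (adjusted p 0.0514 and 0.104), and Nfkb2 kept its call without each library. In a fit of the 9 libraries of NT and day 30 alone, as in the draws, these were 51 and 5, against at most 1 and 3 in a draw without an iEV effect. No such draw held more than 3 iEV calls of any kind. Any iEV effect with more calls could therefore exceed the draws, so this contrast does not measure reversal. At day 4 the counts were 0 and 3, and 0 and 2 in a fit of its own 9 libraries, against at most 2 and 2 in a draw. On the day 30 axis IR_iEV_30d stood at 0.613 ± 0.0923 (SD), against 0.904 to 0.968 in the draws, which lie below 1 because the IR libraries themselves define the axis. On the day 4 axis IR_iEV_4d stood at 0.910 ± 0.0273, within the 0.874 to 0.990 of the draws. Its difference from IR_4d was -0.0899, and -0.0624 without NT replicate 2, -0.0416 without NT replicate 3 and -0.0405 without IR_4d replicate 3. On the axis of the other day, which shares no irradiated library, neither position moved towards NT by more than the spread between libraries in the main setting. The IR_iEV_30d libraries stood at 0.526 on the day 4 axis against 0.528 for IR_30d (exact permutation p = 1). The IR_iEV_4d libraries stood at 0.403 on the day 30 axis against 0.332 for IR_4d, further from NT (exact permutation p = 0.1, the smallest possible). At a mean of at least 5 CPM this difference was -0.0136, in the other direction. In that setting IR_iEV_30d also moved towards NT on the day 4 axis, by more than the SD between libraries in the main setting, as given below.

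**Figure D4:**
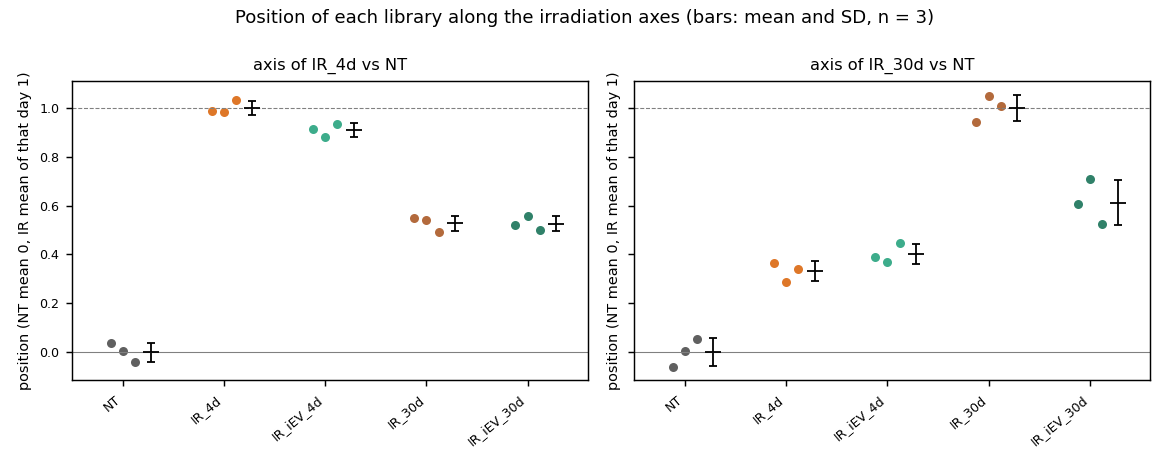
Position of each of the 15 libraries (y axis, NT mean 0 and the IR mean of that day 1) along the axis of day 4 (left, 224 genes) and of day 30 (right, 718 genes) by group (x axis); points are libraries and bars are mean and SD. On the right IR_iEV_30d stands at 0.613, between IR_4d at 0.332 and IR_30d at 1.

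Between the irradiated groups, 1092 genes differed, 772 higher and 320 lower in IR_30d than in IR_4d. Interferon-stimulated genes were higher in 47 of 51 members, or 48 adjusted over the list alone (median 1.40, camera adjusted p = 3.18e-43, and adjusted p = 0.0166 with an estimated correlation). Antigen presentation genes were higher in 22 of 25, or 22 adjusted over the list alone (median 1.03, camera adjusted p = 1.09e-27, and adjusted p = 0.0193 with an estimated correlation). T and NK cell markers were higher in 8 of 26 members, or 16 adjusted over the list alone (median 1.40, camera adjusted p = 3.16e-12, and adjusted p = 0.0166 with an estimated correlation). Tubule products were higher in 17 of 27 and lower in 1, or 17 and 1 adjusted over the list alone (median 1.03, camera adjusted p = 7.11e-11, and adjusted p = 0.262 with an estimated correlation). Of the p53 targets 9 of 40 were lower; adjusted over the list alone 2 were higher and 14 lower (median -0.15, camera adjusted p = 0.000578, and adjusted p = 0.178 with an estimated correlation). The sublingual list differed as well, with a median of -5.49 (camera adjusted p = 0.0144, and adjusted p = 0.481 with an estimated correlation). For sublingual gland markers the adjusted p was 0.243 without IR_4d replicate 1. The count became 727, 539 and 693 without IR_4d replicates 1 to 3 and 677, 652 and 574 without IR_30d replicates 1 to 3. It was 2280 in its own fit, 520 with sublingual and adipose levels as covariates and 376 without the libraries high in sublingual markers.

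Against NT, glands with iEVs still differed on both days. IR_iEV_4d had 371 changed genes, 217 higher and 154 lower, and IR_iEV_30d had 177, 105 higher and 72 lower. The p53 targets were higher in 23 of 40 members at day 4 (median 0.89, camera adjusted p = 6.97e-35, and adjusted p = 0.000329 with an estimated correlation). At day 30 they were higher in 16 (median 0.66, camera adjusted p = 5.74e-30, and adjusted p = 0.000643 with an estimated correlation). Adjusted over the list alone 26 were higher and 1 lower at day 4, and 24 higher at day 30. In IR_iEV_30d antigen presentation genes were higher in 13 of 25 members, or 17 adjusted over the list alone (median 0.71, camera adjusted p = 1.2e-19, and adjusted p = 0.069 with an estimated correlation). Matrix genes were lower in 15 of 42. Adjusted over the list alone 1 was higher and 21 lower (median -0.41, camera adjusted p = 6.85e-12, and adjusted p = 0.165 with an estimated correlation). In IR_iEV_4d adipose markers had a median of 4.02, with 15 of 19 higher adjusted over the list alone (camera adjusted p = 2.16e-10, and adjusted p = 0.51 with an estimated correlation). Parotid markers had a median of 6.05, with 4 of 7 higher adjusted over the list alone (camera adjusted p = 0.00173, and adjusted p = 0.402 with an estimated correlation). With sublingual and adipose levels as covariates the adjusted p was 0.0872 for parotid gland markers and 0.614, with the direction reversed, for adipose tissue. The day 4 count became 797, 196 and 135 without NT replicates 1 to 3 and 208 and 188 without IR_iEV_4d replicates 1 and 2. It was 828 with DESeq2, 106 in its own fit and 55 with sublingual and adipose levels as covariates. The day 30 count became 114 and 113 without NT replicates 1 and 2. It was 393 with DESeq2, 58 in its own fit and 102 without the libraries high in sublingual markers.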

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

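Chosen only after the result was seen were the tests of whether 1 library makes up the interferon or ribosomal pattern, the sum over kallikreins, the test of neighbouring glands for the tubule products, the counts of list members among the 20 genes, and the fits with tissue covariates or without libraries high in sublingual markers as alternatives for the counts; the tests of parotid tissue were added after the patterns were seen but before their own values were.

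The effect of iEVs differed between the days for 20 genes by a test of the difference itself (edgeR, adjusted p under 0.05), all 20 with a lower effect at day 30. As log2 differences they were Ifi206 -3.11, Oas3 -2.80, Oas2 -2.64, Ifit3 -2.60, Rtp4 -2.31, Cmpk2 -1.99, Ifit1 -1.92, Irf7 -1.83, Gbp3 -1.82, Cfb -1.82, Hsd11b1 -1.51, Siglec1 -1.49, Ccdc80 -1.37, Sdc3 -1.32, Bst2 -1.28, Nfkb2 -1.12, C1qa -1.04, Ifitm3 -1.03, C1qb -0.98 and Slc39a14 -0.64. Of the 20, 9 are on the interferon list, which holds 51 of the 16042 genes tested (one-sided Fisher's exact p = 2.57e-18, adjusted over 40 lists 1.03e-16). On the macrophage list, with 34 genes tested, are 2 of them (Fisher's exact p = 0.000809, adjusted 0.0162). Genes are not independent, so these p-values are too small. The count became 9 without IR_30d replicate 2, 12 without IR_30d replicate 3, 106 with DESeq2, 9 with tissue covariates and 7 without the libraries high in sublingual markers. Of the 106, 17 were higher at day 30 and 20 were among the 20 genes. Of the 7, 2 were higher and 2 were among the 20 genes. A fit of its own gave 29, of which 3 were higher. Over 100 regroupings of the libraries within each day, the real one and a random draw of others, 3 gave 20 or more genes, the real one included. This is a share under the 0.05 set beforehand. The others of these 3 gave 52 and 56 genes, more than the real one, so a structure of the samples is not excluded. The effect of iEVs differed for 18 lists, and IR_30d differed from IR_4d for 18 lists and 1092 genes. The latter comparison has no NT group matched to each day, so a changed irradiation effect cannot be told apart from other differences between the collection days. Of these lists, 1 and 4 kept their call with an estimated correlation. Over all 40 lists fry called 1 and 10, and 2 of those 10 were not called by camera.

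For 4 lists the iEV effect passed in opposite directions on the 2 days, and the difference itself passed. Its median was -1.39 for interferon-stimulated genes (camera adjusted p = 2.94e-46, and adjusted p = 0.0259 with an estimated correlation), -0.68 for macrophage markers (camera adjusted p = 1.42e-13, and adjusted p = 0.288 with an estimated correlation), -0.93 for cell cycle genes (camera adjusted p = 1.58e-08, and adjusted p = 0.568 with an estimated correlation) and -0.27 for matrix genes (camera adjusted p = 0.000162, and adjusted p = 0.568 with an estimated correlation). Without the libraries high in sublingual markers the difference lost its call for cell cycle and proliferation and for extracellular matrix and fibrosis. At day 4 alone both lists changed direction in that fit, which keeps 1 library each in IR_4d and IR_iEV_4d. The day 4 call of extracellular matrix and fibrosis ended without IR_4d replicate 1 or 2 or IR_iEV_4d replicate 2 or 3 (camera adjusted p 0.118, 0.229, 0.27 and 0.299). Its day 30 call ended without IR_iEV_30d replicate 3 (0.144). With tissue covariates the day 4 values were 0.268 for cell cycle and proliferation and 0.36 for matrix genes. For 3 lists IR against NT passed in opposite directions on the 2 days, and IR_30d against IR_4d passed as well. The median of IR_30d against IR_4d was 1.40 for interferon-stimulated genes, 1.03 for antigen presentation and 0.84 for macrophage markers (camera adjusted p = 7.67e-19, and adjusted p = 0.0761 with an estimated correlation). Here too no NT group was matched to each day.

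The first pattern weighed is that interferon-stimulated genes were higher with iEVs at day 4 and lower at day 30. Macrophage markers moved the same way, but with their level as a covariate the median difference was -0.924 (-1.03 to -0.645 leaving out each library), against -1.39 without it, which argues against a different macrophage share as the whole cause. Of the 34 macrophage markers tested, 32 had at least 1 CPM in IR_30d and 4 of the list are also in another list; part of the pattern may follow macrophage content. Sublingual and adipose tissue as covariates left the median at -1.44 (-1.50 to -0.927), and the parotid level as covariate at -1.37 (-1.46 to -1.30). These argue against sublingual, adipose or parotid tissue as the whole cause. Leaving out each of 12 libraries left it at -1.25 or further from 0. The interferon list stood at 2.56 (mean log2 CPM) in IR_iEV_4d and 2.63 in IR_iEV_30d, against 1.79 in IR_4d and 3.25 in IR_30d. The IR libraries are the baseline of each iEV comparison, so the change of sign follows mostly the difference between the IR groups. Of the 20 genes whose iEV effect differed, 18 were also called higher in IR_30d than in IR_4d. Both contrasts use the same IR libraries, so choosing genes by the first favours this overlap. An effect of iEVs that differs with time remains a hypothesis, since the collection day and the number of weekly doses change together.

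The second pattern weighed is that tubule products were higher in IR_30d and lower with iEVs, with a median of -0.85 in IR_iEV_30d against IR_30d for this test. The summed CPM of Klk1 and the Klk1b genes was lower by a log2 difference of -0.906 (-1.06 to -0.822 leaving out each library), which argues against reads that only moved between paralogs. In libraries with a sublingual level under 2 the median was -1.16 (-1.22 to -1.09). This argues against sublingual tissue for the fall in IR_iEV_30d replicates 1 and 3, the libraries kept. The tubule list level of replicate 2, left out, was 9.30 (mean log2 CPM), above the IR_30d mean of 9.23. A deeper fall without it could be foreseen, and replicate 2 itself showed no fall in list level. Its summed CPM of Klk1 and the Klk1b genes was 99755, below each IR_30d library (138414, 158149 and 159108). With the parotid level as covariate the median was -1.03 (-1.10 to -0.873). Bpifa2 had 1358 CPM in IR_iEV_30d replicate 2, the library with the high tubule list level. It had 12.3 and 5.94 CPM in replicates 1 and 3, and 296 CPM in IR_30d replicate 2. A deeper fall with this covariate could be foreseen too. The covariate therefore argues against parotid tissue only for the fall in IR_iEV_30d replicates 1 and 3. Of the 16 genes of the sublingual list 9 were tested, 5 had at least 1 CPM in IR_30d, and Dcpp3 had 1568 CPM in IR_iEV_30d replicate 2. Under 3 other scalings the median closest to 0 was -0.823, which argues against scaling by a few abundant genes. A treatment effect on tubule cells or on their number remains a hypothesis, with no test of the latter.

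The third pattern weighed is that ribosomal protein genes were higher with iEVs at day 30, with a median of 0.22. It exceeded that of 10000 lists matched on exonic length and expression by 0.197 (0.159 to 0.228 leaving out each library), which argues against length bias as the whole cause. Across genes, which are not independent replicates, the Spearman correlation of exonic length with the change was -0.128 (-0.148 to -0.0598), so a difference in RNA quality or a shift of short transcripts may contribute and stays open. The lowest median without 1 of the 6 libraries was 0.191. A treatment effect is untested beside it.

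With 6 libraries there are 10 splits, too few for a share under 0.05, so only the real count and the highest other count can be given. These were 224 and 2 for IR_4d against NT, 718 and 1 for IR_30d against NT, 128 and 0 for IR_iEV_30d against IR_30d, 1092 and 0 for IR_30d against IR_4d, 371 and 15 for IR_iEV_4d against NT and 177 and 3 for IR_iEV_30d against NT. In each, 1 split, the real one, reached the real count. For IR_iEV_4d against IR_4d 2 of 10 splits did, and another gave 26 against 5. That split set IR_4d replicate 3 and IR_iEV_4d replicates 1 and 2, the libraries with adipose levels of 3.55, 3.31 and 4.78, against the rest, and points to a structure of the samples.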

How the results depend on the processing

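The alternatives with tissue covariates and without libraries high in sublingual markers were chosen after seeing the data. No gene named in the 4 main comparisons that passed in the main fit or in the alternative reversed its direction there. Changes of sign in genes that passed in neither were not counted. DESeq2 size factors and upper quartile scaling kept every count within 1.5 times and moved the median of all genes by at most 0.027 log2. Of the 16 genes with the largest changes, 10 at IR_4d against NT, 12 at IR_30d against NT and 2 at IR_iEV_30d against IR_30d passed without each library in turn, as did 0 of 5 at IR_iEV_4d against IR_4d, where 1093 genes had an unadjusted p under 0.05. For IR_4d against NT, IR_30d against NT, IR_iEV_4d against IR_4d and IR_iEV_30d against IR_30d, 10, 13, 0 and 9 passed with tissue covariates and 12, 14, 0 and 12 without the libraries high in sublingual markers. At these depths 3 libraries per group missed many of the 1.5-fold changes planted in the simulated data (37, 32, 36 and 37% recovered). Leaving out libraries both lowered and raised counts, and the cause was not tested.

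Counts that moved over 1.5 times were, with DESeq2, 435 for IR_4d against NT, 1082 for IR_30d against NT, 30 for IR_iEV_4d against IR_4d, 394 for IR_iEV_30d against IR_30d, 106 for the difference between the iEV effects, 828 for IR_iEV_4d against NT and 393 for IR_iEV_30d against NT. In fits of their own, IR_iEV_4d against IR_4d had 3, IR_iEV_30d against IR_30d 70, IR_30d against IR_4d 2280, IR_iEV_4d against NT 106 and IR_iEV_30d against NT 58. With the replicate block, IR_iEV_4d against IR_4d had 3 and IR_iEV_30d against IR_30d 83. With tissue covariates the counts were 81 for IR_4d against NT, 0 for IR_iEV_4d against IR_4d (713 at an unadjusted p under 0.05), 75 for IR_iEV_30d against IR_30d, 520 for IR_30d against IR_4d, 9 for the difference and 55 for IR_iEV_4d against NT. Without the sublingual libraries they were 127, 307 (IR_iEV_30d against IR_30d), 376 (IR_30d against IR_4d), 7 (the difference) and 102 (IR_iEV_30d against NT). IR_iEV_4d against IR_4d had 0 with limma-voom (1072 unadjusted) and 2 at a mean of at least 5 CPM. Changes of at least 2-fold numbered 106, 233, 3, 24, 409, 122 and 74 for IR_4d and IR_30d against NT, the iEV comparisons at days 4 and 30, IR_30d against IR_4d, and IR_iEV_4d and IR_iEV_30d against NT.

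Leaving out each library gave 116 to 386 (IR_4d against NT), 355 to 604 (IR_30d against NT), 0 to 7 (IR_iEV_4d against IR_4d; 747 unadjusted at 0, without IR_4d replicate 1), 9 to 199 (IR_iEV_30d against IR_30d), 539 to 727 (IR_30d against IR_4d), 9 to 29 (the difference), 135 to 797 (IR_iEV_4d against NT) and 113 to 182 (IR_iEV_30d against NT).

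List calls fell with an estimated correlation from 13 to 2, 17 to 1, 16 to 0, 11 to 0, 18 to 4, 18 to 1, 17 to 1 and 16 to 1 in the 8 comparisons (IR_4d, IR_30d against NT, iEVs at day 4 and day 30, IR_30d against IR_4d, the difference, IR_iEV_4d and IR_iEV_30d against NT), and with fry, which tests whether a list moves 1 way on balance, the calls over all 40 lists numbered 7, 11, 1, 6, 10, 1, 4 and 5. For IR_iEV_4d against NT 11 lists passed with tissue covariates and 11 to 22 leaving out each library, and for IR_iEV_30d against NT 9 without the sublingual libraries.

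In the 4 main comparisons and the difference, these lists, which passed in the main fit or under the alternative, changed direction. The adjusted p under the alternative is given where no group is left with 1 library. Without the sublingual libraries they were, for IR_4d against NT, cell cycle (1.73e-08) and immediate early genes (0.000364); for IR_iEV_4d against IR_4d, cell cycle (0.00272), matrix (0.0209), glucocorticoid-responsive genes (0.0338), adipose (0.484) and muscle (0.0765); and for the difference, senescence (0.959), cytokines (0.0246) and muscle (0.399). With covariates it was adipose in IR_4d against NT (0.397). Leaving out a library, the range was 0.0255 (reversed, without NT replicate 1) to 0.835 for cell cycle in IR_4d against NT. In IR_iEV_4d against IR_4d it was 1.57e-08 to 0.788 for oxidative phosphorylation (reversed at 0.663 without IR_iEV_4d replicate 2), 0.000161 to 0.717 for ribosomal proteins (reversed without IR_iEV_4d replicate 1) and 9.9e-05 to 0.516 for immediate early genes (reversed without IR_4d replicate 3). It was 4.49e-06 to 0.966 for oxidative phosphorylation in the difference (reversed without IR_iEV_4d replicate 3).

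The difference in axis position, iEV minus IR, moved on the day 4 axis to -0.132 with the 500 genes of lowest p and to -0.0260 at a mean of at least 5 CPM, and from -0.104 to -0.0405 leaving out each library. At a mean of at least 5 CPM it was -0.481 on the day 30 axis (against -0.387), -0.0136 (reversed) for day 4 libraries on the day 30 axis and -0.0610 for day 30 libraries on the day 4 axis. Leaving out each library these last 2 ran from 0.0319 to 0.112 and from -0.0411 to 0.0137.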

Other observations

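Some further lists were called by camera in IR_30d against NT, and each of those given here lost its call with an estimated correlation. Replication-dependent histones had 2 of 7 members higher in IR_30d, H1f2 (0.73 ± 0.18) and H2bc4 (0.69 ± 0.17), also 2 adjusted over the list alone (median 0.73, camera adjusted p = 0.00745, and adjusted p = 0.25 with an estimated correlation). H1f2 lost its call without each library but NT replicate 3 (adjusted p up to 0.126), and H2bc4 without NT replicate 2 or 3 or IR_30d replicate 2 or 3 (up to 0.145). Without the libraries high in sublingual markers H1f2 had an adjusted p of 0.111. Senescence genes had 5 of 36 members higher in IR_30d and 8 adjusted over the list alone (median 0.42, camera adjusted p = 0.000251, and adjusted p = 0.25 with an estimated correlation), among them the chemokine Ccl8 (3.42 ± 0.61), with an adjusted p of 0.0758 without the libraries high in sublingual markers. Endothelial markers had a median of -0.27 over 25 members in IR_30d, with 2 lower adjusted over the list alone (camera adjusted p = 0.00631, and adjusted p = 0.464 with an estimated correlation). The adjusted p for endothelium was 0.151 without NT replicate 1, 0.0668 without IR_30d replicate 1 and 0.099 without the libraries high in sublingual markers.

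A hypothesis set before the data were examined was that iEVs move irradiation-changed genes back on both days, tested on changes that share no irradiated library. Of the 718 genes changed at day 30, 401 (55.8%) had an opposite iEV change at day 4, against at most 59.1% in the other assignments of the day 4 libraries (two-sided exact permutation p = 0.4 over 20 assignments). Of the 224 genes changed at day 4, 120 (53.6%) had an opposite iEV change at day 30, against at most 60.7% in the other assignments (exact permutation p = 0.8). The smallest p these assignments allow is 0.1, so 6 libraries are too few to decide, and the real assignment did not give the largest share on either day.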
